A study of Mus musculus with 12 samples.

How the data were processed

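Gene expression was measured in quadriceps muscle of 12 male mice aged 6 weeks, of the genotype utrn+/-;mdx on the C57BL/10 background per the labels. The mice formed 4 groups of 3 biological replicates: untreated, spironolactone plus lisinopril, eplerenone plus lisinopril, and prednisolone, with each mouse on its own array. Doses, routes and ages were taken from the labels' protocols. These protocols describe RNA isolation with TRIzol, DNase treatment, column clean-up, linear amplification, and biotin labelling with the GeneChip WT PLUS kit for single-channel Affymetrix arrays.

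The deposited values are log2 signals that the authors made with RMA (background adjustment, quantile normalization between arrays and probe set summary) in Affymetrix Expression Console, followed by Transcriptome Analysis Console, per the submitters' processing notes. Versions of these programs, the RMA variant, the annotation release and the genome build are not given in the sources used here. The table holds 65587 transcript clusters, with no missing value and a range of 1.61 to 19.93. In each array 1.27% to 1.34% of clusters lie above 16, the log2 ceiling of a 16-bit scanner, so the values were rescaled at some step that the notes do not describe. Differences are therefore differences of the deposited log2 values, and a fold is a fold on that scale. Array medians over the tested clusters ran from 5.70 to 5.81.

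Clusters were paired with genes through the platform's probe table, which lists 32530 of them. Exactly 1 symbol was given for 30412 clusters (30084 distinct symbols, 247 of them measured by more than 1 cluster), and these were tested. For 827 clusters the symbol was updated through the gene ID, and 22630 clusters had their gene ID in the gene annotation used for this. The 2118 clusters with several symbols and the 33057 without a symbol were left out of the main tests and enter only where all clusters, clusters without exactly 1 symbol or globin clusters are named. No dim clusters were removed in the main analysis, and background or detection values were not used here.

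Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, after reading with the package data.table (version 1.17.8). All 6 pairwise comparisons were made with the moderated two-sided test of eBayes without an intensity trend. Adjustment was by Benjamini-Hochberg over the 30412 clusters, at a threshold of 0.05. The fit had 8 residual and 2.94 prior degrees of freedom, a median residual SD of 0.16 and a median SE of 0.13 per comparison. With 3 arrays per group, precision is limited by the number of arrays, and an exact permutation test of 3 against 3 arrays cannot give a p below 0.1, so the moderated test was used. A limma F-test asked whether the 4 groups differed at all. Counts at a fold of 2, the threshold that the study design names, are given without a test and also with an unadjusted p under 0.05. Groups were called non-overlapping when every array of 1 group lay beyond every array of the other.

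For the 37 gene lists, each gene was represented by its cluster with the highest mean. Lists with at least 5 measured members were tested by camera with its preset correlation of 0.01, and by fry and camera with an estimated correlation as alternatives, each adjusted over the lists. The number of list members past the threshold is given over all clusters and when adjusted over the list alone. The lists cover glucocorticoid-responsive, mineralocorticoid receptor-responsive and renin-angiotensin genes; muscle atrophy, myogenesis, fast and slow fibres, the dystrophin complex, ion channels and the neuromuscular junction; matrix, cytokines, interferon response and markers of immune and other cell types; metabolism, growth signalling, cholesterol and polyamines; and cell cycle, clock, immediate-early, heat shock and oxidative stress genes. Lists share members, so they are not independent.

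Genes were named by a rule. In each comparison it takes the 10 largest rises and the 10 largest falls among clusters past the threshold whose groups did not overlap, leaving out predicted-gene and small RNA symbols, which are counted only. Where fewer than 5 passed in a direction, clusters with a fold of at least 1.5 and the smallest p filled up to 5 and are reported as not past the threshold. For each list the rule adds the members past the threshold or the 4 with the smallest p, of which the text names a part. In every comparison it adds 20 fixed genes: Fkbp5, Tsc22d3, Per1, Zbtb16, Klf15, Nr3c1, Nr3c2, Hsd11b1, Sgk1, Ace, Agt, Agtr1a, Fbxo32, Trim63, Dmd, Utrn, Col1a1, Cd68, Myh3 and Spp1. Spp1 had no cluster with exactly 1 symbol, and the other 19 are given as a range where they did not pass. The direct comparison of the combinations adds the genes named for either against untreated.

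Log2 changes of the 3 treatments against untreated were correlated by Pearson r across clusters. Because these comparisons share the untreated arrays, the same values were computed in 100 simulations without any effect (seed 1) and from single arrays stripped of their group means.

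The fit was tested on simulated data with the spread of these arrays and with each gene drawn independently. Changes of 0.5, 1 and 2 on the log2 scale were recovered in 31.3%, 89.9% and 98.4% of cases for spironolactone plus lisinopril against untreated. The same steps gave 21.2%, 91.8% and 98.6% for eplerenone plus lisinopril and 28.9%, 88.7% and 100% for prednisolone. Of all calls 3.95%, 5.33% and 4.17% were false. With no change simulated limma called 0 clusters in each of the 6 comparisons. Camera called a simulated shift of -0.50 in the interferon list (adjusted p = 5.13e-32) and 0 other lists. Because the simulated genes were independent, these counts do not test the calls, or the preset correlation of camera, where genes move together. The shifted clusters were drawn at random, and all groups had the same spread. Recovery is therefore that of a typical cluster and need not hold for clusters with a larger spread. Against untreated, 14 of the 241 clusters at a fold of 2 passed for spironolactone plus lisinopril. For eplerenone plus lisinopril it was 4 of 199.

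Alternatives tried were an intensity trend, arrays centred on their medians, quantile normalization, array weights, the upper portion of clusters by mean signal (15206 above the median of 5.76), and all 65587 clusters. Further ones were a replicate block, only the 6 arrays compared, a plain analysis of variance, a fold of 1.5, group medians, Spearman correlation, camera on ranks, the mean of a gene's clusters, and leaving out each array in turn. After the data were seen, 2 more were added: leaving out the 2 arrays with the most adipocyte signal, and untreated array 1 as the only control. No array was left out of the main analysis.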

Results

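Quadriceps RNA was profiled in 6-week-old male dystrophic mice, which carried the mdx mutation of the dystrophin gene and were heterozygous for a utrophin mutation. The 12 mice formed 4 groups of 3: untreated, spironolactone plus lisinopril, eplerenone plus lisinopril, and prednisolone. Treatment ran from 4 to 6 weeks of age. The combinations were given in medicated pellets (lisinopril at 20 mg/kg per day with spironolactone at 100 or eplerenone at 200 mg/kg per day), and prednisolone was given at 1.5 mg/kg per day in water. Untreated mice ate normal chow. The set held neither healthy mice nor a group on pellets without drug, so each effect below is measured within dystrophic muscle. Of the measured transcript clusters, 30412 were paired with exactly 1 gene symbol and tested. The comparisons, thresholds, gene lists and the rule for naming genes were chosen before the data were examined. Changes are given as log2 differences ± SE, with n = 3 arrays per group throughout, and 3 arrays per group limit their precision to a median SE of 0.13.

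The broadest response was to prednisolone, and the first question was how it changed dystrophic muscle against no treatment. Prednisolone raised 979 clusters and lowered 963, and 475 of the 1942 carried predicted-gene or small RNA symbols. With quantile normalization the split was 1233 and 852, and with the array medians made equal it was 895 and 872. Inflammatory genes were among the falls. Il1b, which encodes a proinflammatory interleukin, fell by 4.75 ± 0.95 (adjusted p = 0.0171) and Cxcl9, a chemokine induced by interferon gamma, fell by 3.68 ± 0.51 (adjusted p = 0.00401). Il6, Il33 and Ccl8 fell by 2.18, 2.30 and 1.92, while Cxcl13, which attracts B cells, rose by 3.28 ± 0.60 (adjusted p = 0.0123). Of the 41 measured cytokines and chemokines 13 fell and 1 rose (25 and 1 when adjusted over the list alone), and 27 did not pass. Of the 35 interferon-response genes 29 fell (33 over the list alone), among them Bst2 at -2.41, Oas2 at -2.29, Ifit1 at -1.91 and Rsad2 at -1.77. The median change of that list was -1.19 (camera adjusted p = 1.44e-29; adjusted p = 0.185 with an estimated correlation). Cytokines had a median of -0.97 (camera adjusted p = 1.85e-11; adjusted p = 0.185 with an estimated correlation). That list was high in untreated arrays 2 and 3 (median deviation 0.71 in each) and not in untreated array 1 (0.00466), and against array 1 alone the median for cytokines and chemokines was -0.22, still past camera. Slfn4, itself a gene induced by interferon, fell by 3.22 ± 0.73 and passed in 13 of 23 alternatives. Measured from untreated array 1 alone, Il1b was at -1.94, Il33 at -0.90 and Slfn4 at -1.48, none of them past the threshold. Antigen presentation followed, with 7 of 22 genes lower (11 over the list alone), including B2m at -0.72, H2-K1 at -0.93 and H2-Eb1 at -1.41. Of 35 macrophage and monocyte markers 8 fell (14 lower and 1 higher over the list alone): the lipopolysaccharide co-receptor Cd14 by 1.55, Fcgr1 by 2.23, Tyrobp by 1.26 and the scavenger receptor Mrc1 by 1.22. Among 20 neutrophil markers Hdc (-2.87) and Retnlg (-2.54) fell, and 11 were lower and 2 higher over the list alone. Against untreated array 1 alone the median of the neutrophil markers was 0.0155, with the opposite camera direction, as untreated arrays 2 and 3 carried the high values. T and NK cell markers had 3 of 26 lower, with Thy1 at -0.89 (4 over the list alone).

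Some stress-induced transcription factors and some glucocorticoid-responsive genes were also lower in muscle given prednisolone. Nr4a3 and Nr4a1, orphan nuclear receptors of the immediate-early class, were at -3.48 ± 0.54 and -2.91 ± 0.60. Of the 26 immediate-early genes 9 fell (18 over the list alone), Zfp36 and Myc among them at -2.35 and -1.79. Several genes that glucocorticoids usually induce were lower, not higher. Per1 fell by 3.37 ± 0.55 (adjusted p = 0.00769), and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, fell by 1.81 ± 0.31 (adjusted p = 0.00883). Cebpd was at -3.10 ± 0.41, Ddit4 at -2.99 ± 0.68 and Nfkbia at -2.25 ± 0.23. Fkbp5 (0.65 ± 0.31, adjusted p = 0.257) and Sgk1 (-0.91, adjusted p = 0.0845) did not pass, nor did the glucocorticoid receptor gene Nr3c1 (-0.30, adjusted p = 0.282). Over the 36 glucocorticoid-responsive genes 10 fell, 3 rose and 23 did not pass (16 and 7 past over the list alone; adjusted p = 0.374 with an estimated correlation). Of this list, Fbxo32 (1.52), Nr1d1 (0.98) and Lpin1 (0.74) were higher. That list was not lower with prednisolone only: its median was -0.45 there (camera adjusted p = 0.00706), -0.53 with spironolactone plus lisinopril (1.23e-05; 0.347 with an estimated correlation) and -0.45 with eplerenone plus lisinopril (8.6e-06; 0.182 with an estimated correlation). The glucocorticoid list lay above its mean over the 12 arrays in all 3 untreated arrays (median deviation 0.10, 0.23 and 0.54). In the circadian list of 20, which shares Per1, 8 genes fell and 4 rose (9 and 5 over the list alone). Arntl (1.57 ± 0.21), Npas2 (1.28), Clock (0.41) and Nr1d1 (0.98) were higher. Lower were Dbp (-1.28), Nr1d2 (-0.93) and Per3 (-0.84). Of the 20 mineralocorticoid receptor-responsive genes 5 fell, including Adamts1 at -1.53 and Ccn2 at -1.84, and 2 rose (6 and 3 over the list alone).

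Under prednisolone some matrix genes fell and some genes of metabolism, ion channels and the dystrophin complex rose, while most members of these lists did not pass. Col1a1, the main fibrillar collagen gene, fell by 0.66 ± 0.07 (adjusted p = 0.00208), Col3a1 by 0.66, Fn1 by 0.81 and Postn by 0.66, and Thbs1, a matricellular glycoprotein, fell by 3.42 ± 0.41. Altogether 13 of 44 matrix and fibrosis genes fell (21 lower and 1 higher over the list alone; camera adjusted p = 8.71e-10; adjusted p = 0.0851 with an estimated correlation). Mitochondrial genes rose, 11 of 37 (28 over the list alone), with Ndufv1 at 0.77 ± 0.10, Cyc1 at 0.90 and the coactivator Ppargc1b at 0.76. Of 33 genes of fatty acid oxidation 12 rose (16 over the list alone), among them Cpt1b by 0.97, Acadvl by 0.85 and the lipid droplet gene Plin5 by 0.69. Glucose handling showed 7 of 25 higher (13 over the list alone), led by the glucose transporter gene Slc2a4 at 1.34 and glycogen synthase Gys1 at 0.97. The chloride channel Clcn1 (1.21) and the potassium channel Kcnj2 (2.16 ± 0.36) were among 8 of 27 ion channel and calcium handling genes that rose (10 over the list alone). So were the calcium channel subunit Cacna1s (1.02) and the calcium pump regulator Sln (1.95 ± 0.41). Dmd itself rose by 0.75 ± 0.18 (adjusted p = 0.0331), as did Sgca by 0.94, Ano5 by 1.03, Sntb1 by 1.17 and Cav3 by 0.74. In total 8 of 22 genes of the dystrophin complex and membrane repair rose, while Sntb2 fell by 0.79 (11 and 2 over the list alone). Utrn was at -0.12 (adjusted p = 0.59). The atrophy ubiquitin ligase Fbxo32 rose by 1.52 ± 0.36 (adjusted p = 0.0313) while the related ligase gene Trim63 was at 0.38 (adjusted p = 0.448). Of 34 atrophy genes 5 rose, with Capn3 at 0.84, Asb2 at 1.16 and Foxo4 at 0.45, and 1 fell (9 and 4 over the list alone). Agt, the angiotensin precursor, was the single member of 22 renin-angiotensin genes that passed, at 1.08 ± 0.17 (adjusted p = 0.00703; 1 over the list alone). Other large rises were Aldh1a1, a retinaldehyde dehydrogenase, by 2.59 ± 0.19 (adjusted p = 0.000193), the carbonic anhydrase Car14 by 2.40 ± 0.24, the methyltransferase Mettl21e by 2.15, Odf3l2 by 1.90, Ctxn3 by 1.86, Inmt by 1.83 and the mitochondrial transfer RNA mt-Tk by 1.75. Erdr1 fell by 3.31 ± 0.22 (adjusted p = 0.000193).

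**Figure D1:**
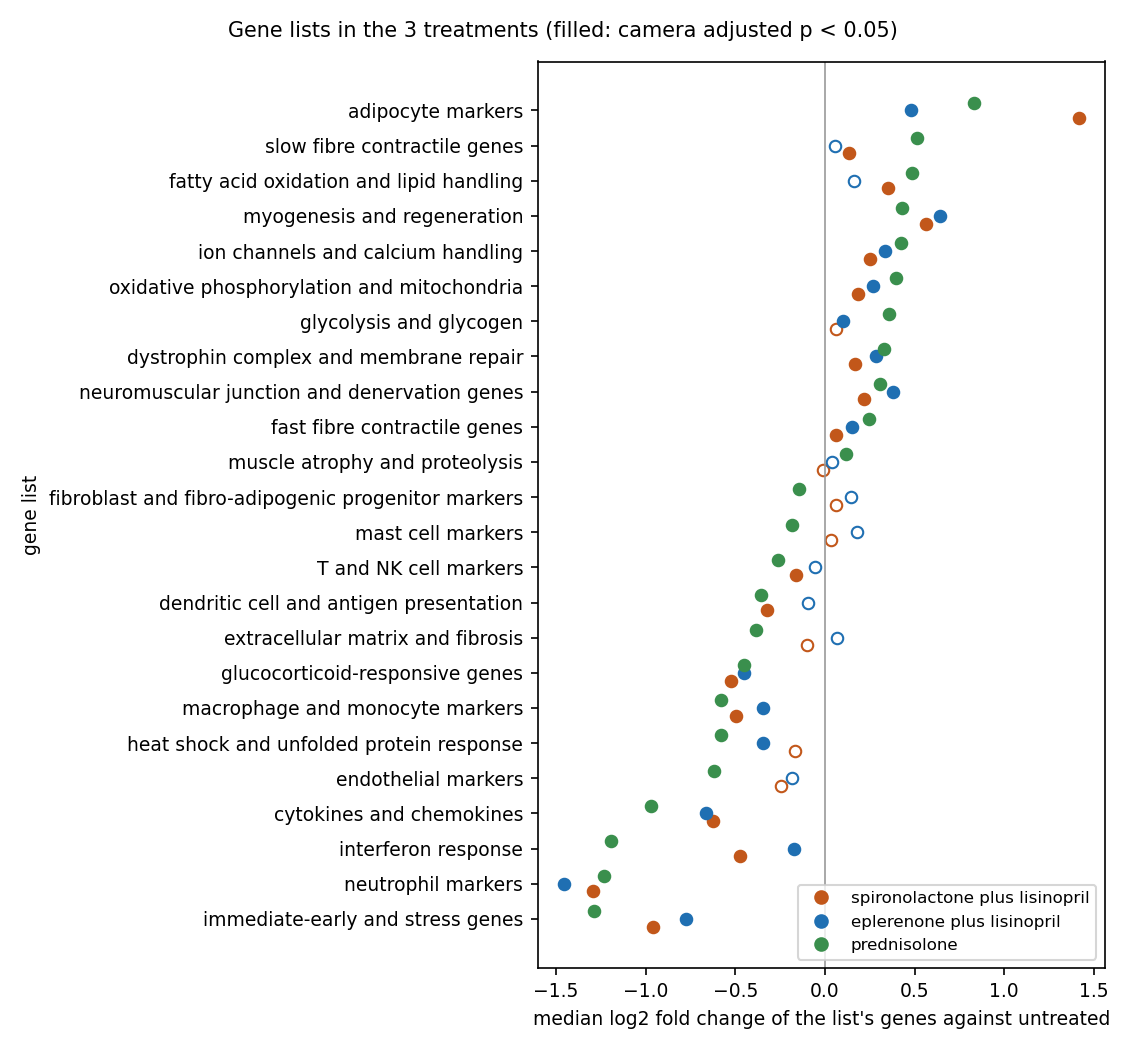
Median log2 change of the 24 gene lists past camera in prednisolone, shown for each treatment against untreated. Interferon genes stood at -1.19 in prednisolone, -0.47 in spironolactone plus lisinopril and -0.17 in eplerenone plus lisinopril.

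Across the 37 gene lists, camera called 24 for prednisolone (11 higher, 13 lower), fry called 15, and with the correlation between genes estimated from 12 arrays 0 passed (smallest adjusted p = 0.0851; 9 at an unadjusted p under 0.05). Lists past camera as higher, with their medians, were mitochondria (0.40; adjusted p = 0.185 with an estimated correlation), fatty acid oxidation (0.49; 0.185), glycolysis (0.36; 0.225), ion channels (0.42; 0.185), dystrophin complex (0.33; 0.185) and fast fibre genes (0.25; 0.374; 5 of 25 rose, 10 over the list alone, with Myoz1 at 1.06 and Ryr1 at 0.75). Also higher were slow fibre genes (0.51; 0.409; 2 of 21 rose, 4 over the list alone, with Smtnl1 at 1.53), myogenesis (0.43; 0.409; 3 of 29 rose, 3 over the list alone, Mef2c at 0.72 and Myh8 at 0.93), neuromuscular junction genes (0.31; 0.374; 3 of 20 rose and 1 fell, 3 and 1 over the list alone, with Chrnb1 at 0.84 and Rapsn at 0.69), atrophy genes (0.12; 0.374) and adipocyte markers (0.83; 0.536; 0 of 25 passed, also over the list alone). Lower were the interferon and cytokine lists, the matrix list, immediate-early genes (-1.29; adjusted p = 0.185 with an estimated correlation), antigen presentation (-0.36; 0.185) and T and NK markers (-0.26; 0.185). Lower too were macrophage markers (-0.58; 0.374), neutrophil markers (-1.23; 0.388), endothelial markers (-0.62; 0.374; 6 of 21 fell, 12 over the list alone, Cdh5 by 1.48), heat shock and unfolded protein genes (-0.58; 0.416; Xbp1 fell by 0.79, 1 of 23; 8 lower and 1 higher over the list alone; median 0.0288 and the opposite camera direction against untreated array 1 alone), glucocorticoid-responsive genes (-0.45; 0.374), mast cell markers (-0.18; 0.43; 1 of 12) and fibroblast markers (-0.15; 0.565; 2 of 19 fell and 1 rose, 4 and 1 over the list alone). Further lists, 13 in all, did not pass camera. Among them were polyamine genes (median -0.35), the circadian list (-0.26), erythroid genes (-0.29, 1 of 6 lower), mineralocorticoid receptor-responsive genes (-0.19), B cell (-0.06, 2 of 15 lower), tendon (0.07), cholesterol (0.13), cell cycle (-0.04) and oxidative stress genes (-0.01). In the oxidative stress list 1 of 20 was lower, Hmox1 at -1.55 ± 0.39, with 6 lower and 1 higher over the list alone. The remaining 4 were Schwann cell (-0.06, 1 of 13 lower, 2 lower and 1 higher over the list alone), renin-angiotensin (-0.01), smooth muscle (0.02, 1 of 16 lower) and growth signalling genes (0.05). In the growth list Igfbp3 was higher at 1.59 and 3 of 26 were lower, Irs2 at -1.43 among them (3 higher and 5 lower over the list alone). Several medians depended on single arrays. Slow fibre genes were at 0.32 without untreated array 3, still past camera, and their median deviation was -0.03 in prednisolone array 1 against 0.64 and 0.36 in arrays 2 and 3. Medians were nearer to 0 against untreated array 1 alone for macrophage markers (-0.29), glucocorticoid-responsive genes (-0.18), ion channels (0.19), glycolysis (0.18) and fast fibre genes (0.02), all still past camera, and for atrophy genes (0.0662), no longer past. With 1 array left out, 5 lists were no longer past camera in at least 1 case: myogenesis genes (0.23 without untreated array 3), adipocyte markers (0.15 without prednisolone array 1), mast cell markers and fibroblast markers (each -0.11 without untreated array 1), and atrophy genes. Adipocyte markers also differed between arrays of 1 group: the median deviation was 1.33 in prednisolone array 1 but -0.69 in prednisolone array 2.

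The fold of 2 that the study design names was reached by 514 clusters in prednisolone against untreated (159 higher, 355 lower); 476 of these had an unadjusted p under 0.05 and 343 passed the adjusted threshold. The groups did not overlap for 26.7% of clusters, where chance gives 10%. Without prednisolone array 2 the limma count was 456, and without prednisolone array 1 it was 656. Without untreated array 3, 2 or 1 it was 842, 938 or 2643. A plain analysis of variance called 0. Measured from untreated array 1 alone, other named genes also had changes more than 1.5 times smaller than in the main comparison and did not pass. Among the falls these were Hdc (-1.59), Retnlg (-1.32), Ccn2 (-1.13), Tyrobp (-0.82), Mrc1 (-0.64), Hmox1 (-0.51) and Xbp1 (-0.37). Among the rises they were Ctxn3 (1.24), Odf3l2 (1.16), Clcn1 (0.71), Nr1d1 (0.62), Ano5 (0.59), Capn3 (0.50) and Dmd (0.33). Hmox1 and Retnlg passed in 9 of 23 alternatives each. Of 13 fixed genes that did not pass, none lay beyond -0.91 (Sgk1) or 0.94 (Myh3).

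**Figure D2:**
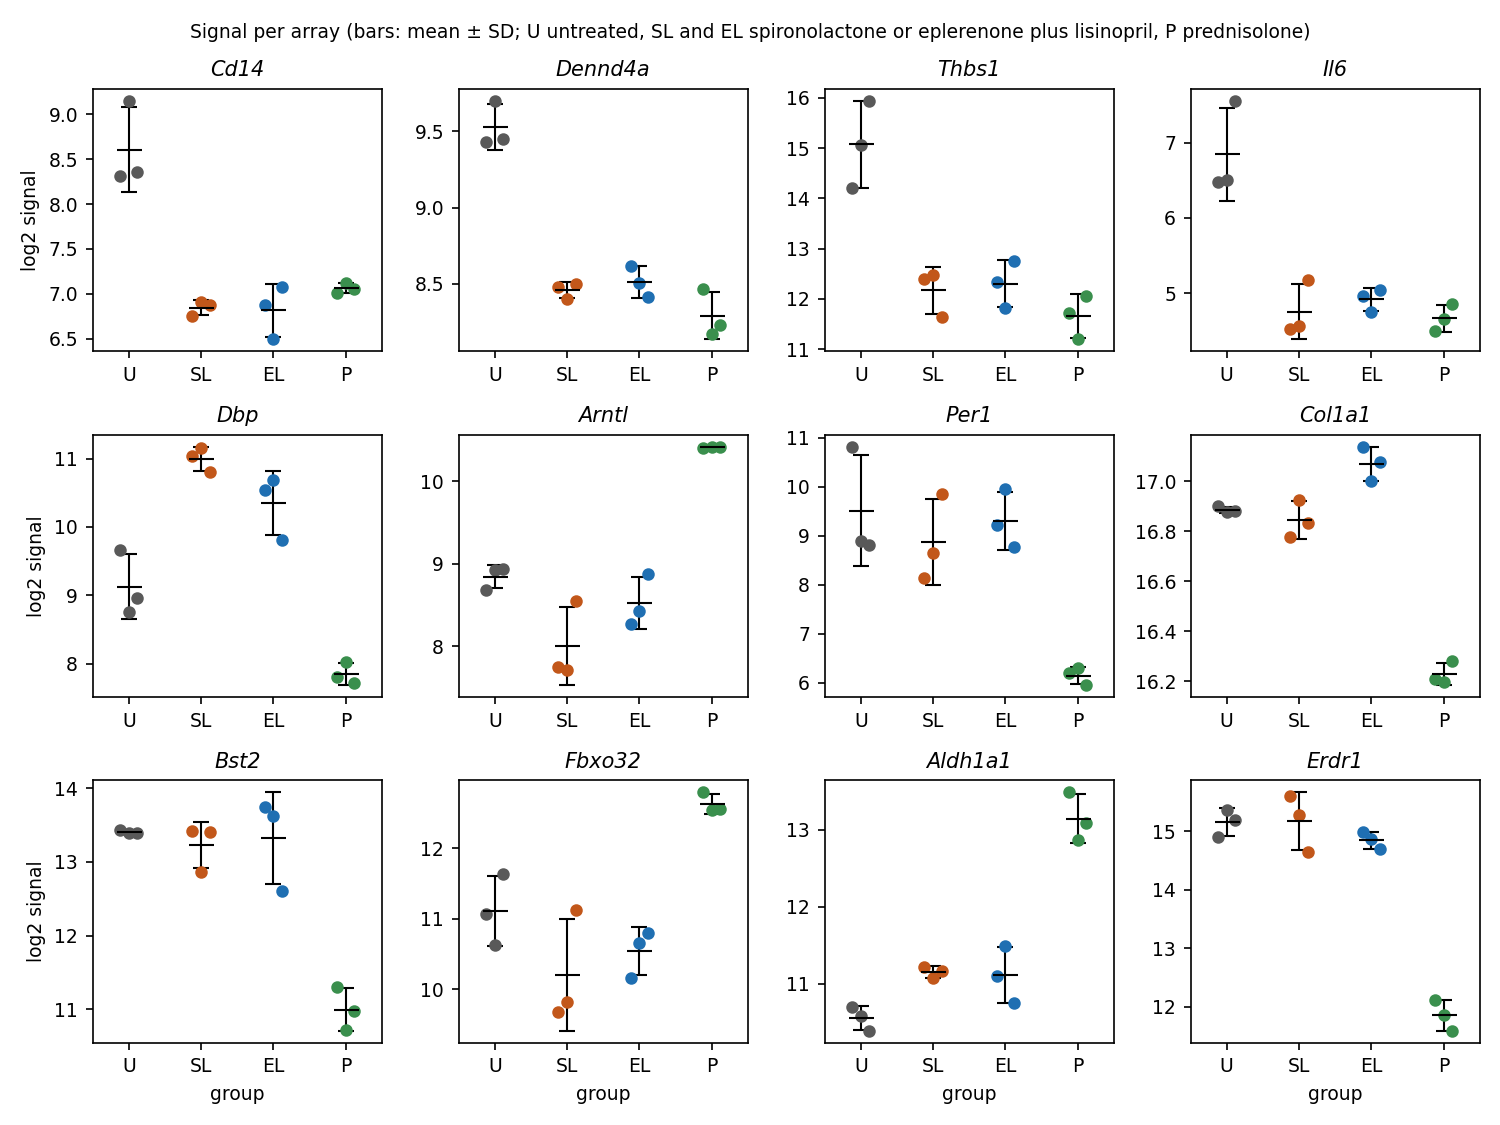
Signal of 12 genes in each array, with mean and SD per group. Cd14 and Dennd4a were lower in all 9 treated arrays than in any untreated array (log2 change -1.76 and -1.07 in spironolactone plus lisinopril), while Erdr1 was low only in the prednisolone arrays (-3.31).

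Spironolactone plus lisinopril, compared with no treatment, asked whether mineralocorticoid receptor antagonism with an angiotensin-converting enzyme inhibitor reached the same genes. The combination raised 6 clusters and lowered 19. Clock genes were among the rises: Dbp, a circadian output factor, rose by 1.87 ± 0.25 (adjusted p = 0.0282), the nuclear receptor gene Nr1d1 by 1.28 ± 0.18 (adjusted p = 0.0384) and Per3 by 1.25 ± 0.17 (adjusted p = 0.0282). Sntb1, which encodes a syntrophin of the dystrophin complex, rose by 1.46 ± 0.22 (adjusted p = 0.0419). Gabre, a subunit gene of a GABA receptor, did not pass (0.59, adjusted p = 0.0683). Inflammatory genes were again among the falls. Thbs1 fell by 2.90 ± 0.41 (adjusted p = 0.0384), Il6 by 2.09 ± 0.27 (adjusted p = 0.028), Zfp36, which drives decay of cytokine messages, by 2.16 ± 0.33 (adjusted p = 0.0482) and Cd14 by 1.76 ± 0.21 (adjusted p = 0.028). The urokinase receptor gene Plaur fell by 1.45, the costimulatory ligand gene Cd80 by 1.32, and Ell2 and metallothionein Mt1 each by 1.12. Lower too were Dennd4a at -1.07 ± 0.10 (adjusted p = 0.0194), Trim25 at -0.96, Nfil3 at -0.86 and Nfe2l2 at -0.73. None of the 19 measured fixed genes passed; they lay between -0.90 (Fbxo32, adjusted p = 0.263) and 1.13 (Myh3), and Tsc22d3 was at -0.84 (adjusted p = 0.241).

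By group, 21 of 37 lists passed camera for spironolactone plus lisinopril, 13 higher and 8 lower; fry called 5, and 0 passed with an estimated correlation (smallest adjusted p = 0.297; 4 at an unadjusted p under 0.05). The interferon list had a median of -0.47 (camera adjusted p = 6.63e-11; adjusted p = 0.347 with an estimated correlation); 0 of 35 genes passed over all clusters and 16 over the list alone, with Oas1a at -0.96 and Stat2 at -0.98. Immediate-early genes had a median of -0.96 (camera adjusted p = 3.23e-10; adjusted p = 0.347 with an estimated correlation) with Zfp36 as the 1 gene of 26 past the threshold and 11 over the list alone, Nr4a3 at -2.31 and Fosl2 at -1.87 among them. Of the cytokines only Il6 passed (14 lower over the list alone), and Il1b was at -4.05 ± 0.95 (adjusted p = 0.151). Against untreated array 1 alone the median of cytokines and chemokines was -0.0977 and that of neutrophil markers -0.11, neither past camera. Neutrophil markers had a median of -1.29 with 0 of 20 past the threshold and 6 over the list alone. S100a8 (-4.10 ± 1.19), S100a9 (-3.79 ± 1.07) and Hdc (-2.54) had wide errors. From untreated array 1 alone S100a8 was at -0.54, Hdc at -1.25 and Il1b at -1.25. The neutrophil list was high in untreated arrays 2 and 3 (median deviation 1.72 and 1.37) and not in untreated array 1 (-0.21). On the rising side, myogenesis genes had a median of 0.56 (adjusted p = 0.347 with an estimated correlation) with 0 of 29 past the threshold and 3 over the list alone, Mef2c at 0.71 and Chrnd at 0.91 among the nearest. Mitochondrial genes had a median of 0.19 (adjusted p = 0.347 with an estimated correlation), with 0 of 37 past the threshold, 1 over the list alone, and Ppargc1b at 0.74 (adjusted p = 0.0755). The mitochondrial median was 0.0573 against untreated array 1 alone, still past camera, and without untreated array 3 the myogenesis median was 0.33. The circadian list, at a median of 0.21, was at 0.0442 and not past camera against untreated array 1 alone. The circadian list had 3 genes higher and 1 lower of 20 (8 and 3 over the list alone), with Arntl at -0.84 and Npas2 at -1.01. Adipocyte markers had a median of 1.42 with 0 of 25 past the threshold and 1 over the list alone; Ucp1 was at 3.31 ± 0.77 and Scd1 at 2.74 ± 0.88. The list was highest in spironolactone plus lisinopril array 3 (median deviation 2.24, against 0.40 and -0.45 in arrays 1 and 2), and its median without that array was 0.72, still past camera. The matrix list did not pass camera (median -0.10, adjusted p = 0.226), with Thbs1 as its 1 gene of 44, also over the list alone.

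At a fold of 2 spironolactone plus lisinopril had 241 clusters (67 higher, 174 lower), 197 of them with an unadjusted p under 0.05 and 14 past the adjusted threshold, and 4929 clusters had an unadjusted p under 0.05. Groups did not overlap for 20.4% of clusters against 10% by chance. The count of 25 moved with single arrays. Without untreated array 3, spironolactone plus lisinopril array 1 or prednisolone array 3 limma called 0. Without untreated array 1 or spironolactone plus lisinopril array 3 it called 534 or 165. Prednisolone array 3 is outside this comparison and enters it only through the shared estimate of the spread. A count of 0 therefore need not mean that 1 array carried the differences. Cd14 nonetheless stayed between -1.91 and -1.47 under 23 alternatives, of which 13 called it, and Dennd4a passed in 15 of 23. Cd80 and Mt1 were at -0.82 and -0.74 against untreated array 1 alone, neither past the threshold.

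Eplerenone plus lisinopril was compared with untreated muscle in the same way and gave a smaller set, 2 clusters higher and 7 lower (3 and 6 with the array medians made equal). Sgta, a co-chaperone gene, rose by 0.53 ± 0.07 (adjusted p = 0.0254) and Shisa4 by 0.84 ± 0.11 (adjusted p = 0.05, just under the threshold before rounding). Chrnb1, an acetylcholine receptor subunit gene (1.04, adjusted p = 0.061), Tbc1d7 (0.70, adjusted p = 0.0706) and Reep1 (0.76, adjusted p = 0.0783) did not pass. Cd14 fell by 1.79 ± 0.21 (adjusted p = 0.0235), Cd80 by 1.39 ± 0.17 and Ell2 by 1.12 ± 0.14 (both adjusted p = 0.0254). Dennd4a fell by 1.01 ± 0.10 (adjusted p = 0.0143), the oxidative stress regulator Nfe2l2 by 0.75 ± 0.09 and Rel, which encodes a subunit of nuclear factor kappa B, by 0.69 ± 0.07 (adjusted p = 0.0143). Il6 (-1.93, adjusted p = 0.0501) and Mt1 (-1.20, adjusted p = 0.0501) missed the threshold narrowly, and Thbs1 (-2.77, adjusted p = 0.0706) and Zfp36 (-1.85, adjusted p = 0.104) missed it too. The 19 fixed genes lay between -0.79 (Tsc22d3, adjusted p = 0.311) and 0.83 (Myh3), and none passed.

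Camera called 18 lists for eplerenone plus lisinopril (10 higher, 8 lower), fry called 11, and with an estimated correlation 0 passed (smallest adjusted p = 0.182; 10 at an unadjusted p under 0.05). Myogenesis genes had the smallest camera p (median 0.64, camera adjusted p = 2.69e-12; adjusted p = 0.182 with an estimated correlation), with 0 of 29 genes past the threshold and 9 over the list alone, Mef2c at 0.64 and Chrnd at 0.99 among them. Mitochondrial genes had a median of 0.27 (adjusted p = 0.235 with an estimated correlation), Cyc1 at 0.73 (adjusted p = 0.118), and 3 of 37 passed over the list alone. That median was 0.0879 against untreated array 1 alone, still past camera. Dystrophin complex genes had a median of 0.29 (adjusted p = 0.182 with an estimated correlation) with 0 of 22 past the threshold and 6 over the list alone, Sgca at 0.59. The list median was 0.0684 against untreated array 1 alone and not past camera, and without untreated array 3 the myogenesis median was 0.41. Cytokines (median -0.66), immediate-early genes (-0.77) and neutrophil markers (-1.46) were lower, each with adjusted p = 0.182 with an estimated correlation. No member passed over all clusters and 14, 7 and 12 did over the lists alone, Il1b at -4.54 ± 0.95, S100a8 at -5.15 ± 1.19, S100a9 at -4.39 and Hdc at -2.53. Against untreated array 1 alone the median of cytokines and chemokines was -0.0369, no longer past camera, and that of neutrophil markers was -0.17. Single genes moved too: from that array Il1b was at -1.73, S100a8 at -1.59 and Cd80 at -0.88, none past the threshold, and immediate-early genes had a median of -0.51 without untreated array 3, still past camera. The interferon list was at -0.17 (camera adjusted p = 0.0332; adjusted p = 0.714 with an estimated correlation), and without untreated array 3 it was at -0.04 with the opposite camera direction. Matrix genes did not pass (median 0.07, camera adjusted p = 0.218), nor did the circadian list (camera adjusted p = 0.145), in which Dbp was at 1.22 and Nr1d1 at 1.10 (adjusted p = 0.0949). At a fold of 2 there were 199 clusters (52 higher, 147 lower), 183 with an unadjusted p under 0.05 and 4 past the adjusted threshold; 4087 had an unadjusted p under 0.05 and 16.9% did not overlap, against 10% by chance. Limma called 0 clusters without untreated array 3, eplerenone plus lisinopril array 1 or array 2, 1 without its array 3, and 432 without untreated array 1.

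**Figure D3:**
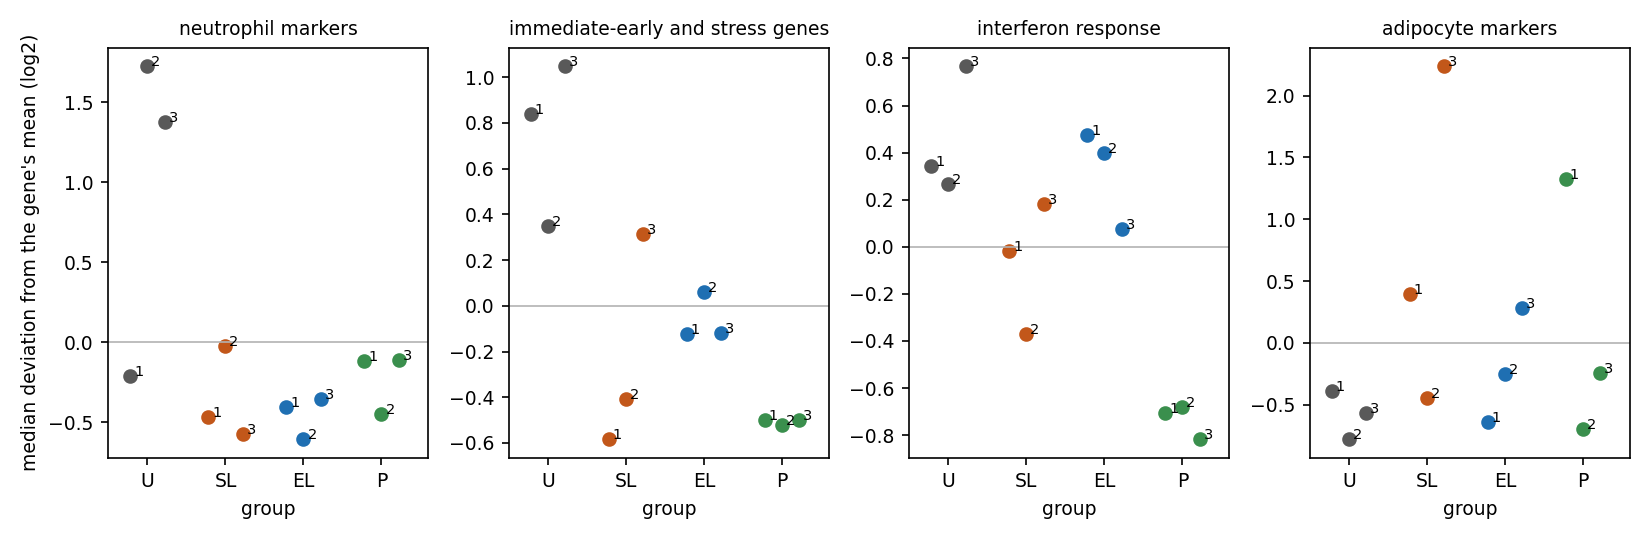
Median deviation of 4 gene lists in each array, with the replicate number beside each point. Neutrophil markers were high in untreated arrays 2 and 3 (1.72 and 1.37) and not in array 1 (-0.21), and adipocyte markers were highest in spironolactone plus lisinopril array 3 (2.24).

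The 2 antagonists were compared directly to ask whether the choice of drug mattered. Both are steroidal blockers of the mineralocorticoid receptor. Eplerenone carries a methyl ester in place of the thioacetyl group of spironolactone, and also an epoxide. The doses of the 2 antagonists differed, so drug and dose are not separated. Limma called 0 of 30412 clusters (smallest adjusted p = 0.998), with 1365 at an unadjusted p under 0.05 and 0 by a plain analysis of variance. For the 22 genes named as largest changes or as fill-ins for either combination against untreated, the difference lay between -0.44 (Chrnb1) and 0.65 (Per3), and 13 of the 95% intervals held 0. Genes named above only as list members are not among the 22, and 6 of them lay outside this range: Ucp1 and Npas2, as given below, S100a8 (1.05 ± 1.19), Oas1a (-0.62), Stat2 (-0.56) and Arntl (-0.53). For Cd14 the interval was -0.42 to 0.49, for Dennd4a -0.28 to 0.18, for Il6 -0.76 to 0.43 and for Thbs1 -1.04 to 0.78. Intervals without 0, none of them past the adjusted threshold, belonged to Dbp (0.09 to 1.21), Per3 (0.28 to 1.03), Sntb1 (0.14 to 1.09), Rel (0.14 to 0.46), Gabre (0.20 to 0.62), Sgta (-0.42 to -0.13), Shisa4 (-0.59 to -0.08), Chrnb1 (-0.77 to -0.11) and Tbc1d7 (-0.48 to -0.02). Each of these genes was named for its change with 1 combination in these same arrays. That choice moves the difference away from 0 in the direction seen, and the intervals take no account of it. Smallest unadjusted p values among the folds of at least 1.5 belonged to Ppbp (0.97), Hlf (0.84), Ppara (0.67), Per3 and Rassf9 (0.82) on the side of spironolactone. On the side of eplerenone they belonged to Spanxn4 (-0.86), Chac1 (-1.29), Mx1 (-0.62), Npas2 (-1.02) and Traj61 (-0.79). Among the fixed genes none passed, from -0.43 (Per1) to 0.58 (Zbtb16). Camera placed 12 lists apart, 7 higher and 5 lower with spironolactone; fry called 0 (2 at an unadjusted p under 0.05) and 0 passed with an estimated correlation (smallest adjusted p = 0.656; 2 at an unadjusted p under 0.05). Interferon genes were lower with spironolactone (median difference -0.36, camera adjusted p = 2.4e-11; adjusted p = 0.717 with an estimated correlation), with 0 of 35 past the threshold and 1 over the list alone. Adipocyte markers were higher (0.74, adjusted p = 0.717 with an estimated correlation), Ucp1 at 2.76 ± 0.77. That difference leaned on spironolactone plus lisinopril array 3, with a median deviation of 2.24 against 0.40 and -0.45 in arrays 1 and 2. The eplerenone plus lisinopril arrays stood at -0.64, -0.25 and 0.28. Matrix genes were slightly lower with spironolactone (-0.10, adjusted p = 0.708 with an estimated correlation), with Col1a1 at -0.22. Only 25 clusters reached a fold of 2 (19 higher, 6 lower), 4 with an unadjusted p under 0.05, and 9.68% did not overlap, against 10% by chance. Without spironolactone plus lisinopril array 2 that fold count was 76, and the limma count was 0 with any of the 12 arrays left out.

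**Figure D4:**
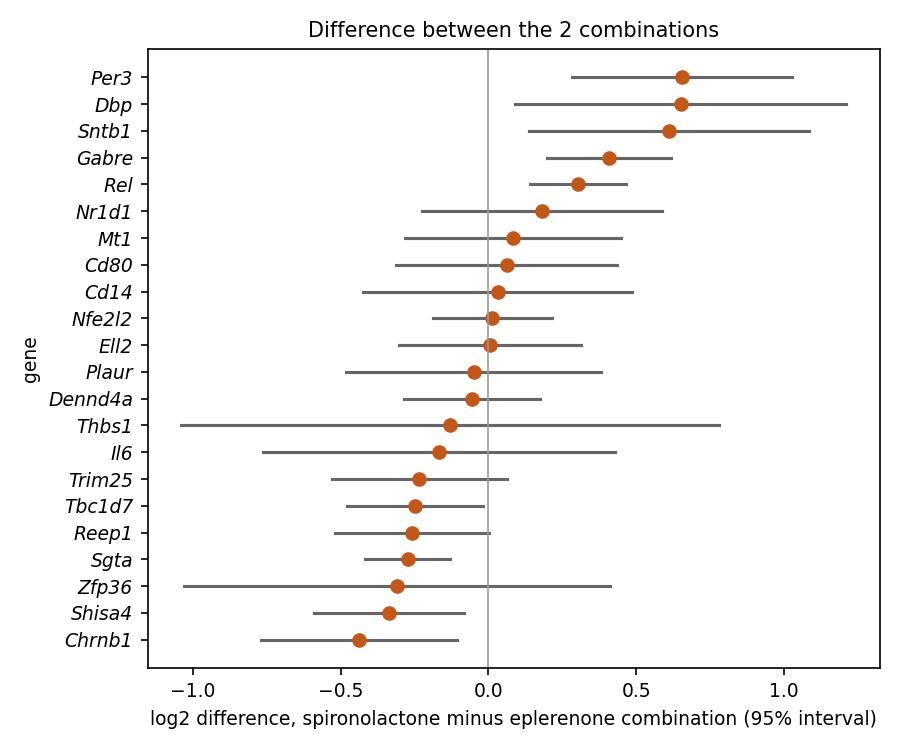
Difference between the 2 combinations with 95% intervals for the 22 genes named as largest changes or fill-ins for either against untreated. The genes were chosen from these same arrays, and the intervals take no account of that choice. The highest of these was Per3 at 0.65 and the lowest Chrnb1 at -0.44.

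Prednisolone was then set against each combination, the comparison of a glucocorticoid with mineralocorticoid receptor antagonism. Against spironolactone plus lisinopril 250 clusters differed, 137 higher and 113 lower with the combination. With the array medians made equal the split was 296 and 75, and with quantile normalization 99 and 131, so the balance of directions depends on the scaling. Matrix genes were higher with the combination: Col1a1 by 0.62 ± 0.07 (adjusted p = 0.00639), Postn by 0.85, Col14a1 by 0.96 and Col3a1 by 0.55, although Eln was lower at -0.79 (6 of 44 higher and 1 lower; 14 and 2 over the list alone; adjusted p = 0.0788 with an estimated correlation). Fbxo32 was lower with the combination at -2.42 ± 0.36 (adjusted p = 0.0191), as were Asb2 at -1.51, Pdk4, a kinase gene that restrains pyruvate oxidation, at -2.82 ± 0.49, Plin5 at -0.63 and the fast fibre gene Myoz1 at -0.97. Clock genes parted widely. Dbp was higher by 3.15 ± 0.25 (adjusted p = 0.000686), Per3 by 2.09, Nr1d2 by 1.68 and Per2 by 1.62. Arntl, Npas2 and Clock were lower at -2.42 ± 0.21, -2.29 and -0.50 (6 of 20 higher and 3 lower; 11 and 4 over the list alone; adjusted p = 0.463 with an estimated correlation). Per1 differed by 2.73 without passing (adjusted p = 0.0516). Interferon genes were higher with the combination in 4 of 35 (21 over the list alone; adjusted p = 0.463 with an estimated correlation), Bst2 by 2.24, and B2m was higher by 0.60 and Cxcl9 by 2.75. Erdr1 (3.33 ± 0.22), Col15a1 (1.80), Gpr65 (1.44) and the receptor tyrosine kinase gene Ret (1.32) were higher as well. Lcn2 (-3.06), Cxcl13 (-3.05), the complement gene C7 (-2.60), Ppp1r3c (-2.45), Odf3l2 (-2.44), Car14 (-2.23) and Agt (-0.95) were lower. Camera placed 22 lists apart (16 higher, 6 lower), fry 1, and 0 passed with an estimated correlation (smallest adjusted p = 0.0789; 3 at an unadjusted p under 0.05). At a fold of 2 there were 166 clusters (93 higher and 73 lower, or 121 and 59 with the array medians made equal and 79 and 89 with quantile normalization). Of the 166, 147 had an unadjusted p under 0.05 and 62 passed the adjusted threshold, and 24.0% did not overlap, against 10% by chance. The limma count was 23, 25, 30 and 55 without prednisolone array 2, spironolactone plus lisinopril array 1, prednisolone array 1 and spironolactone plus lisinopril array 2.

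Against eplerenone plus lisinopril 185 clusters differed from prednisolone, 114 higher and 71 lower with the combination (172 and 48 with the array medians made equal). Collagen and matrix genes again stood higher, 8 of 44 (20 higher and 1 lower over the list alone), with Col1a1 at 0.84 ± 0.07 (adjusted p = 0.00118), Col1a2 at 0.59, Col3a1 at 0.74 and Postn at 0.89. This was the single list of the study that passed with an estimated correlation (median 0.45, camera adjusted p = 4.51e-17; adjusted p = 0.0125 with an estimated correlation). Interferon genes were higher in 16 of 35 (33 over the list alone; median 1.02, camera adjusted p = 7.56e-40; adjusted p = 0.146 with an estimated correlation), among them Bst2 by 2.32, Oas2 by 1.69, Rsad2 by 1.69 and Irf7, a master factor of the interferon response, by 1.56. Ifi213 was higher by 1.72 and Cxcl9 by 2.94. B2m (0.62) and Tap1 (0.76) were 2 of the 3 antigen presentation genes higher out of 22 (12 over the list alone). Per1 was higher by 3.17 ± 0.55 (adjusted p = 0.0349), Dbp by 2.50 ± 0.25 and Per3 by 1.44, while Arntl, Npas2 and Clock were lower at -1.89, -1.28 and -0.51 (5 of 20 clock genes higher and 3 lower; 10 and 4 over the list alone). Igf1 was higher by 0.62 and Col15a1 by 1.98. Lower with the combination were Fbxo32 (-2.09 ± 0.36, adjusted p = 0.0321), Agt (-0.91, adjusted p = 0.0488), Aldh1a1 (-2.03), Car14 (-2.18), Mettl21e (-2.09), Inmt (-1.94), Lcn2 (-3.10), Cxcl13 (-3.71), Ppp1r3c (-2.57), Odf3l2 (-2.33) and Plin5 (-0.77). Erdr1 was higher by 3.00 ± 0.22 and Tsc22d3 was at 1.02 without passing (adjusted p = 0.185). Camera placed 19 lists apart (14 higher, 5 lower) and fry 3. At a fold of 2 there were 211 clusters (127 higher, 84 lower; 186 with an unadjusted p under 0.05, 70 past the adjusted threshold), and 19.9% did not overlap, against 10% by chance. Without prednisolone array 2, eplerenone plus lisinopril array 1, prednisolone array 1 or eplerenone plus lisinopril array 2 the limma count was 27, 30, 32 or 50.

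The last question was how far the 3 treatments resembled each other. A limma F-test over the 4 groups called 588 clusters, with 26 when prednisolone array 2 was left out and 1271 without untreated array 1. Cd14, Cd80, Dennd4a, Ell2 and Nfe2l2 were lower than untreated in all 3 treatments, with changes in prednisolone of -1.55, -1.52, -1.23, -1.09 and -0.99. Of the 19 clusters that spironolactone plus lisinopril lowered, 6 of the 7 lowered by eplerenone plus lisinopril were shared (0.00437 expected of independent lists) and 17 were shared with prednisolone (0.602 expected), Thbs1, Il6, Zfp36 and Plaur among them. Of the 6 it raised, prednisolone raised 4, including Sntb1 and Nr1d1 (0.193 expected), and it lowered Dbp and Per3. Eplerenone plus lisinopril shared 6 of 7 lowered clusters with prednisolone (0.222 expected) and both raised ones, Sgta and Shisa4 (0.0644 expected). These lists share the untreated arrays and are not independent, so the expected numbers are no test of sharing. Log2 changes of the 2 combinations correlated at r = 0.811 across clusters, those of prednisolone and spironolactone plus lisinopril at r = 0.670 and those of prednisolone and eplerenone plus lisinopril at r = 0.688. The shared untreated arrays alone gave a mean of 0.50 for each pair in simulated data without any effect, and up to 0.907, 0.880 and 0.834 when single arrays of these data stripped of their group means were drawn. Covariances were 0.0582, 0.0627 and 0.0604 against 0.0137, 0.0136 and 0.0137 in simulated data, and signs were shared by 77.8%, 69.8% and 72.5% of clusters against 66.7% in each simulation. Drawn arrays stripped of their group means gave covariances of 0.0162, 0.0153 and 0.0174 on average and up to 0.0527, 0.0433 and 0.0417 in 100 draws. Covariances exceeded the simulated ones by 0.0445, 0.0490 and 0.0468, and they also lay above the highest of the drawn arrays. The simulation draws each gene independently, however, and the highest draws came much nearer to the observed values. The excess is therefore no estimate of the part that shared controls do not add.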

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

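All 9 tests of explanations below were chosen after the results were seen, while the counts over other splits of the arrays were planned. Among the 35175 clusters without exactly 1 symbol, which the comparisons leave out, 176 were higher in prednisolone than in untreated muscle and 217 lower (limma, adjusted over these clusters; 4573 at an unadjusted p under 0.05), with changes of up to 2.37 and down to -4.99. Of all these changed clusters 30 carried several symbols. The combinations changed 0 (spironolactone, with 3963 at an unadjusted p under 0.05) and 1 (eplerenone, lower, with 3239). Genes behind the clusters without a symbol were not identified.

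Immediate-early genes and neutrophil markers were higher in untreated muscle than in the treated groups by camera with its preset correlation. With an estimated correlation 0 lists passed against untreated in any treatment (smallest adjusted p = 0.0851). For the neutrophil part, untreated array 1 stood at a median deviation of -0.21, below the highest treated array (-0.03), so the size of this part rests on untreated arrays 2 and 3. Prednisolone arrays 1 and 3 (-0.12 and -0.11) also lay above untreated array 1. The eplerenone plus lisinopril arrays (-0.41, -0.61 and -0.36) all lay below it. That the immediate-early part rests on untreated arrays 2 and 3 is argued against, since untreated array 1 stood at 0.84 and the highest treated array at 0.31. Blood left in untreated arrays 2 and 3 is argued against by 4 globin clusters of several symbols: the higher of these arrays lay at -1.26 from untreated array 1 in mean globin deviation (SD within groups 0.80), where neutrophil markers lay at least 1.58 above it. Stress or handling at collection cannot be told apart from treatment: 3 of 3 untreated arrays lay above every treated array (lowest 0.35), as either would give, and the untreated mice also differed in chow from those on pellets.

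Clock genes of opposite phase moved apart between prednisolone and spironolactone plus lisinopril. Direct induction of Per1 by prednisolone would raise it, but its change from untreated was -3.37 with an upper 95% limit of -2.15. No net rise was therefore seen. As a clock gene, Per1 would also move with the time of collection, so direct induction cannot be judged from this difference. A different time of day at collection or a shifted clock stays open. Between prednisolone and spironolactone plus lisinopril, 16 of 16 clock genes of known phase had the sign of their phase, and both explanations predict this. Against untreated, prednisolone moved Nr1d1 (0.98) and Nfil3 (-0.53) the other way and the rest with their phase. Collection times are not in the labels used here. A drug effect on the clock may also give this pattern and was not tested apart from collection time.

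Erdr1 and Gm21887 were low in the 3 prednisolone arrays, at -3.31 and -3.18. Both clusters may read 1 transcript, since their within-group residuals correlated at 0.985. The neighbour Mid1 was also lower, with its 2 clusters at -0.63 (adjusted p = 0.0228) and -0.59 (adjusted p = 0.0548). An equal loss there is argued against, since their lower 95% limits reached -0.94 at the lowest while the upper limit of Erdr1 was -2.81, but a smaller change of the region stays open. An inherited difference between the animals of the groups cannot be told apart from a drug effect, with a gap of 2.53 between the highest prednisolone array and the lowest of the other 9, since litters are not in the labels used here.

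For the F-test over the 4 groups, 1 of 100 splits, the real one, gave 588 clusters and the highest other gave 242. The highest other counts (242, 135 and 70) came from splits that kept the prednisolone arrays together. The result therefore argues against chance mainly for prednisolone and does not show that each of the 4 groups stands apart. For each pair of groups the 10 splits are too few for a share under 0.05. The real counts and the highest other were 25 and 0 clusters for spironolactone plus lisinopril against untreated, 9 and 0 for eplerenone plus lisinopril, 1942 and 0 for prednisolone, 0 and 0 between the combinations, and 250 and 0 and 185 and 0 for the combinations against prednisolone. For camera lists they were, in the same order, 21 and 21, 18 and 22, 24 and 17, 12 and 17, 22 and 16, and 19 and 13. Splits that mix the groups thus gave as many or more camera lists than 3 of the 6 real comparisons.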

How the results depend on the processing

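Most alternatives here were planned, and 2 were chosen after seeing the data: leaving out the 2 arrays with the most adipocyte signal (spironolactone plus lisinopril array 3 and prednisolone array 1), and using untreated array 1 as the only control. Why a count moved was not tested except where the construction of an alternative shows it. Values in series follow the order spironolactone plus lisinopril against untreated, eplerenone plus lisinopril against untreated, prednisolone against untreated, the 2 combinations, spironolactone plus lisinopril against prednisolone, and eplerenone plus lisinopril against prednisolone. The main limma counts were 25, 9, 1942, 0, 250 and 185, the F-test count was 588, and the counts at a fold of 2 were 241, 199, 514, 25, 166 and 211.

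A fold of 1.5 in place of 2 gave 1304, 1030, 2223, 190, 957 and 850 clusters. Counting all clusters, 409, 361, 946, 59, 309 and 367 reached a fold of 2, and limma then called 11 clusters for spironolactone plus lisinopril against untreated and 115 against prednisolone. Array weights raised the limma counts to 40 and 15 for the combinations against untreated, to 990 and 380 against prednisolone, and the F-test to 1262. In the upper portion by mean signal the F-test called 1128, eplerenone plus lisinopril had 19 clusters against untreated and 339 against prednisolone, and spironolactone plus lisinopril had 619 against prednisolone. With only the 6 arrays compared, limma called 0, 0 and 584 clusters against untreated and 37 for spironolactone plus lisinopril against prednisolone. A plain analysis of variance called 0, 1, 0, 0, 0 and 0, and the 1 cluster was not among the 9 of limma. Centring, quantile normalization, group medians and the intensity trend left every total within 1.5 times its main value, but not every count by direction: for spironolactone plus lisinopril against prednisolone, 137 higher and 113 lower became 296 and 75 with centring.

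With the correlation between genes estimated, 0, 0, 0, 0, 0 and 1 lists passed, against 21, 18, 24, 12, 22 and 19 by camera, and fry called 5, 11, 15, 0, 1 and 3. For spironolactone plus lisinopril against prednisolone, camera called 13 lists in the upper portion by mean signal. Estimated from 12 arrays, the correlation made all 63 list calls against untreated weaker, fry made 35 of them weaker, the upper portion 14, centring 4 and ranks 1, while the mean of a gene's clusters and the replicate block left all 63 past the threshold. The size of the list results therefore rests on the preset correlation.

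As a replicate block (a paired fit), the replicate number gave 1 and 2 clusters for the combinations against untreated, 75 and 82 against prednisolone, 267 by the F-test, and 1452 for prednisolone against untreated. Numbers did not pair the arrays, however: after removal of group means, the 18 same-numbered pairs correlated at r = -0.237 to 0.157, 4 of them over 0.1, and 3 of 12 arrays correlated best with an array of their own number. These values show no factor shared by number, and the block uses up residual degrees of freedom.

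With single arrays left out, the limma count ran from 0 (without untreated array 3) to 534 (without untreated array 1) for spironolactone plus lisinopril against untreated, from 0 to 432 (the same arrays) for eplerenone plus lisinopril, and from 456 (without prednisolone array 2) to 2643 (without untreated array 1) for prednisolone. Without prednisolone array 2 or untreated array 1, respectively, it ran from 23 to 328 and from 27 to 264 for the combinations against prednisolone, and from 26 to 1271 for the F-test. It stayed at 0 between the combinations. For spironolactone plus lisinopril against untreated, removing arrays 1, 2 and 3 of its own group left 0, 1 and 165 clusters, those of eplerenone plus lisinopril 7, 14 and 12, those of prednisolone 2, 1 and 0, and untreated array 2 left 11. For eplerenone plus lisinopril against untreated, its own arrays left 0, 0 and 1, those of spironolactone plus lisinopril 3, 3 and 17, and those of prednisolone 3, 4 and 3. Removing the arrays of spironolactone plus lisinopril left 25, 55 and 124 clusters against prednisolone, and removing those of eplerenone plus lisinopril left 30, 50 and 90. Prednisolone array 1 left 30 and 32 of these and 656 against untreated, where untreated arrays 2 and 3 left 938 and 842. The F-test called 278 without untreated array 2 or 3, and 58 and 310 without prednisolone arrays 1 and 3. At a fold of 2 the counts ran from 225 (without untreated array 3) to 409 (without untreated array 1) for spironolactone plus lisinopril, from 164 (without eplerenone plus lisinopril array 2) to 410 (without untreated array 1) for eplerenone plus lisinopril, and from 19 (without eplerenone plus lisinopril array 1) to 76 (without spironolactone plus lisinopril array 2) between them. Camera lists of spironolactone plus lisinopril against prednisolone ran from 12 (without spironolactone plus lisinopril array 3) to 22 (without untreated array 2). The interferon median of eplerenone plus lisinopril against untreated ran from -0.31 (without untreated array 2) to -0.0351 (without untreated array 3), where the camera direction turned (adjusted p = 0.784).

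With the 2 adipocyte-rich arrays left out, limma called 169, 0 and 657 clusters against untreated, 17 and 39 for the combinations against prednisolone, and 68 by the F-test, 40 clusters parted the combinations at a fold of 2, and camera called 12 lists for spironolactone plus lisinopril against prednisolone. With untreated array 1 as the only control, assumed to vary like the other groups, limma called 0, 0 and 146 clusters against untreated and the F-test 126. Of the 63 list calls 43 stayed past the threshold, 16 grew weaker and 4 turned: glycolysis in eplerenone plus lisinopril (median 0.00313), heat shock genes in eplerenone plus lisinopril (0.0645) and prednisolone (0.0288), and neutrophil markers in prednisolone (0.0155). Against that array the neutrophil median was -0.11 in spironolactone plus lisinopril, no longer past the threshold, and -0.17 in eplerenone plus lisinopril, still past it (adjusted p = 0.017), so the size of the neutrophil result depends on untreated arrays 2 and 3. The list of cytokines and chemokines went the same way, with medians of -0.0977 and -0.0369 in the combinations, no longer past the threshold, and -0.22 in prednisolone, still past it. Macrophage markers were at -0.14 and -0.12 in the combinations, no longer past the threshold, and without untreated array 2, which carried their highest signal (0.779), at -0.31 in prednisolone.

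Correlations of the changes were 0.736, 0.589 and 0.627 by Spearman for the 2 combinations, for prednisolone with spironolactone plus lisinopril, and for prednisolone with eplerenone plus lisinopril. Without the adipocyte-rich arrays the first 2 were 0.748 and 0.595, and in the upper portion by mean signal the first was 0.859. Over single arrays left out they ran from 0.746 (without eplerenone plus lisinopril array 2) to 0.872, from 0.619 (without spironolactone plus lisinopril array 3) to 0.757 and from 0.634 (without eplerenone plus lisinopril array 3) to 0.772, each highest without untreated array 1.

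Of 235 results for named genes none changed direction under any alternative. Calls kept their side of the threshold in 233 with the intensity trend, 228 with quantile normalization, 227 with centring, 226 with array weights, 219 in the upper portion, 194 with all clusters, 179 with the replicate block, 151 without the adipocyte-rich arrays, 144 with only the 6 arrays compared, 134 with untreated array 1 alone and 56 by analysis of variance.

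Precision is limited by the number of arrays (median SE 0.13) and by signal (median of tested clusters 5.76). Without background values, dim true signal could not be told from background.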

Other observations

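Prednisolone stood apart from all 3 other groups by limma in 46 clusters that were higher and 62 that were lower. Each of these comparisons uses the same prednisolone arrays, so values peculiar to those arrays move all 3 alike. Of the 46, 17 carried predicted-gene or small RNA symbols, as did 6 of the 62. Beyond the genes named by rule, these were chosen after their values were seen. Higher than untreated were Fhl3 (1.43 ± 0.18), Ttll7 (1.40 ± 0.16), Sbk2 (1.34 ± 0.20), Dapk2 (1.22 ± 0.15), the potassium channel gene Kcng4 (1.22 ± 0.19), the lactate transporter gene Slc16a3 (1.09 ± 0.17) and Mgst3 (1.05 ± 0.14). Lower were interferon-induced genes outside the top falls, such as Ifi209 (-2.02 ± 0.22), Trim30a (-1.97 ± 0.20), Trim30d (-1.95 ± 0.14), Rnf213 (-1.92 ± 0.23), Oasl2 (-1.72 ± 0.17), Eif2ak2 (-1.39 ± 0.15) and Xaf1 (-1.32 ± 0.18), and the lectin gene Lgals9 (-1.56 ± 0.11).

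In all 3 treatments 5 clusters were lower than in untreated muscle and 0 higher by limma. In spironolactone plus lisinopril, eplerenone plus lisinopril and prednisolone Cd14 was at -1.76, -1.79 and -1.55, Cd80 at -1.32, -1.39 and -1.52, Dennd4a at -1.07, -1.01 and -1.23, Ell2 at -1.12, -1.12 and -1.09, and Nfe2l2 at -0.73, -0.75 and -0.99. All 3 comparisons share the untreated arrays, so high values there lower all 3 alike.

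Arrays differed within groups. The first 3 principal components held 27.9%, 15.5% and 12.5% of the variance. Untreated arrays 2 and 3 lay at -45.2 and -40.8 on the first component and untreated array 1 at -12.5, nearer to the treated arrays of the combinations, which ran from -4.78 to 13.5. Array weights were lowest for spironolactone plus lisinopril array 3 (0.626) and untreated array 1 (0.632). Adipocyte deviation was 2.24 in that spironolactone plus lisinopril array and 1.33 in prednisolone array 1, and no other array exceeded 0.40.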
